A study of Drosophila melanogaster with 5 samples.

How the data were processed

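Chromatin was profiled by FAIRE-seq, in which crosslinked, sheared chromatin is phenol-extracted and the DNA that stays free of nucleosomes is sequenced. The series holds 5 libraries of Drosophila melanogaster. Per the labels, 2 came from midline cells sorted by their GFP from embryos aged 6 to 8 hours, 2 from whole OregonR embryos of the same age, and 1 was genomic DNA of adult virgin females, used as input. The sorted cells carried a sim-Gal4 driver and a membrane GFP reporter, so the 2 FAIRE groups differ in strain and in cell dissociation and sorting as well as in cell type.

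Per the submitters' processing notes, the reads went through CASAVA 1.8.2, Bowtie2, SAMtools, bedtools and MACS2 on the dm3 genome build. The role of each tool, the MACS2 settings and the way the input was used are not given in the sources used here. Per the names in the files, the authors called peaks on the pooled replicates of each group and deposited the 10000 highest peaks of each. Each of the 2 lists gives the position of a peak, a numbered name and a score. The deposited score is a whole number whose scale the files do not state, so it was used here only to describe and rank peaks within a list. The files hold no read counts, no signal and no values per replicate, so the depth of each library is unknown and no spread between replicates could be estimated. All intervals and tests below therefore describe the 2 deposited lists, not the variation between embryo collections. The input library had no values of its own among the files used here, and 0 columns of per-sample values were left unused.

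The numbers in the authors' peak names rise along the chromosomes and skip some values. The highest number was 15189 in the midline list and 17552 in the embryo list, so each list was treated as part of a longer set of at least that many calls. This assumes that the numbers were given before the 10000 peaks were selected, which the files do not state. On that assumption, which every value from the longer lists below shares, the skipped numbers count the peaks left out between 2 neighbouring kept peaks, although not their positions.

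A peak was called shared if it overlapped a peak of the other list by at least 1 bp, and otherwise midline-only or embryo-only. The overlap was compared with 1000 circular shifts of each list along its chromosomes, each by at least 5% of the span that the peaks cover. Shares are given with exact Clopper-Pearson 95% intervals, which cover counting error only. Medians of shared and list-only peaks were compared by two-sided permutation tests with 100000 resamples, and chromosome arms by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 5 arms. Agreement of ranks was measured over shared peaks paired by their largest overlap. The named peaks are the 5 highest-scoring peaks of each list-only class, as the rule fixed before the data were examined states for a case without a gene annotation. Coordinates are 1-based on dm3. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

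The reference table supplied with the files is on another build (Release 6) and no coordinates were converted. The planned tests of promoters, gene lists, genes with an excess of peaks and sequence motifs were therefore not run, no gene is assigned to a peak, and the preset gene lists give no result. In their place, tests on windows of 50000 bp were added after the files had been seen. Each window with at least 6 list-only peaks was compared with the genome-wide proportion of midline-only peaks by an exact two-sided binomial test, adjusted by Benjamini-Hochberg with a threshold of 0.05. A second added test counted how often neighbouring list-only peaks belonged to the same class, against 1000 reassignments of the classes within each chromosome arm.

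The procedures were tested on simulated data. A list built with 6000 shared peaks among 10000 returned 6000. The shared peaks were exact copies and the rest were placed clear of embryo peaks, so this checks only the counting. With 487 windows, random classes gave 0 calls, and 13 of 20 windows made wholly midline-only were found, with 0 false calls. Those 20 were drawn from windows with more list-only peaks than the minimum tested, and were altered together. The rate found therefore does not apply to windows at the minimum or to a single uneven window. Alternatives changed the overlap rule (50% reciprocal overlap, or midpoints within 250 bp), the peak width (500 bp around the midpoint), the list length (the 5000 highest-scoring peaks), the measure of strength (peak width) and the window. No sequencing batch is given in the labels, and the pooled lists cannot be split by batch.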

Results

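The data comprised 2 lists of open-chromatin peaks from Drosophila embryos aged 6 to 8 hours, each called by the authors on 2 pooled FAIRE-seq replicates. The first came from sorted midline cells, the neurons and glia and their precursors that form at the midline of the central nervous system. The second came from whole embryos, in which midline cells are a small minority. The comparison asks which open regions are found in midline cells, which in the embryo as a whole, and which in both. Each list held 10000 peaks on the arms 2L, 2R, 3L, 3R and X of dm3. Midline peaks had a median width of 275 bp (interquartile range 199 to 384 bp) and covered 3.17 Mb. Embryo peaks had a median width of 329 bp (224 to 482 bp) and covered 3.91 Mb. The authors' scores ran from 44 to 1009 in the midline list and from 70 to 1645 in the embryo list. The lists are pooled, so there are no replicate values, and read depth is unknown.

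Many peaks were called both in midline cells and in the whole embryo. Of the 10000 midline peaks, 6089 (60.9%, 95% interval 59.9 to 61.8%) overlapped an embryo peak, and 3911 were midline-only. Of the 10000 embryo peaks, 5658 (56.6%, 55.6 to 57.6%) overlapped a midline peak, and 4342 were embryo-only. The 2 shared counts differ because 424 embryo peaks spanned several midline peaks, whereas 37 midline peaks spanned several embryo peaks. The overlapping sequence amounted to 2.02 Mb, which was 63.7% of the midline and 51.6% of the embryo peak sequence. Randomly shifted midline peaks overlapped an embryo peak 580 ± 26 times (SD over 1000 shifts), so the observed overlap was 10.5 times that number. For embryo peaks the shifts gave 568 ± 25 and the ratio was 9.96. No shift reached the observed number in either direction (one-sided permutation p = 0.001, the smallest that the shifts can give). The shifts place peaks anywhere along an arm, so this shows only that the overlap exceeds random placement. When sharing required a reciprocal overlap of 50%, the shared part was 46.8% of each list, under the unshared part.

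Sharing followed the strength of the peak. Among the 1000 highest-scoring midline peaks, 96.6% (95.3 to 97.6%) were shared and 34 were midline-only, whereas 24.7% (22.1 to 27.5%) of the 1000 lowest-scoring were shared. The embryo list ran from 97.2% (96.0 to 98.1%) to 24.3% (21.7 to 27.1%) over the same ranks. Within the midline list, shared peaks had a median score of 136 and midline-only peaks 64. Within the embryo list the medians were 243 for shared and 108 for embryo-only peaks. Both differences were larger than any of 100000 permutations gave (two-sided permutation p = 1e-05 in each list, the smallest they can give). Shared peaks were also wider, with medians of 312 against 221 bp in the midline list and 422 against 228 bp in the embryo list (two-sided permutation p = 1e-05 in each). Of the peaks at least 1000 bp wide, 98.4% of 62 midline peaks and 98.1% of 265 embryo peaks were shared. Each list holds only its highest peaks, and the ranks of shared peaks were related between the lists (below). The counterpart of a weak peak may therefore lie below the limit of the other list, which alone would lower sharing among weak peaks. Wider peaks also meet the overlap rule more easily. These tests cannot separate such effects from a real difference, and strength was not retested at a fixed peak width or by midpoint distance.

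**Figure D1:**
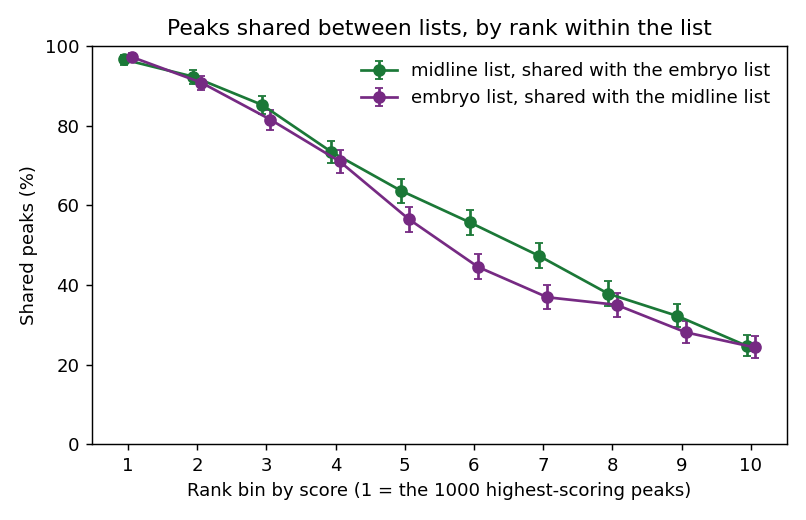
Percent of peaks shared with the other list (y axis) in bins of 1000 peaks ranked by score within their own list (x axis, 1 is the highest). Green points are the midline list, purple points the embryo list, and bars are exact 95% binomial intervals. Both lists fall from over 95% to under 25%.

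The ranks of shared peaks were related between the lists. Over 5633 pairs of overlapping peaks, the ranks by score had a Spearman correlation of 0.59 and a Pearson correlation of 0.53 (two-sided permutation p = 1e-05 for each). This is a correlation across peaks, which are not independent replicates. The number of peaks per 50000 bp window was also related between the lists (Spearman 0.75, Pearson 0.78 over 2185 windows that held a peak). Shared peaks count in both lists, so part of this relation follows from the overlap already given. The densest window was the same in both, at positions 12050001 to 12100000 of 3R, with 30 midline and 23 embryo peaks.

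The strongest midline-only region was on the X. The peak at positions 2690163 to 2690879 had a score of 1009, the highest of the whole midline list, and its nearest peak among the 10000 embryo peaks lay 23.8 kb away. The 60 kb around it held 1 further midline peak, also midline-only, and 1 embryo-only peak. The next region was on 3R, where a midline-only peak at positions 8896864 to 8897318 had a score of 693 and ranked 29. It stood in a dense cluster, since the 60 kb around it held 8 midline-only peaks, 6 midline peaks shared with the embryo and 2 embryo-only peaks. The other 3 lay on 3L at positions 1355034 to 1355708 (score 613), on 3L at 12663058 to 12663550 (score 487) and on 3R at 7483574 to 7484152 (score 453). Their nearest embryo peaks were between 1413 and 2647 bp away. By the peak numbers, the longer embryo list held further peaks between the flanking embryo peaks of all 5 regions (1, 1, 1, 4 and 2, in the order given), at unknown positions. The sorted cells came from another strain than the whole embryos, one that carries transgenes, and no gene annotation of dm3 was used, so the genes at these positions are not named. Whether the 2 highest peaks lie in sequence that the transgenes also carry, such as that of the sim driver, was not determined, and extra copies would raise a score.

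**Figure D2:**
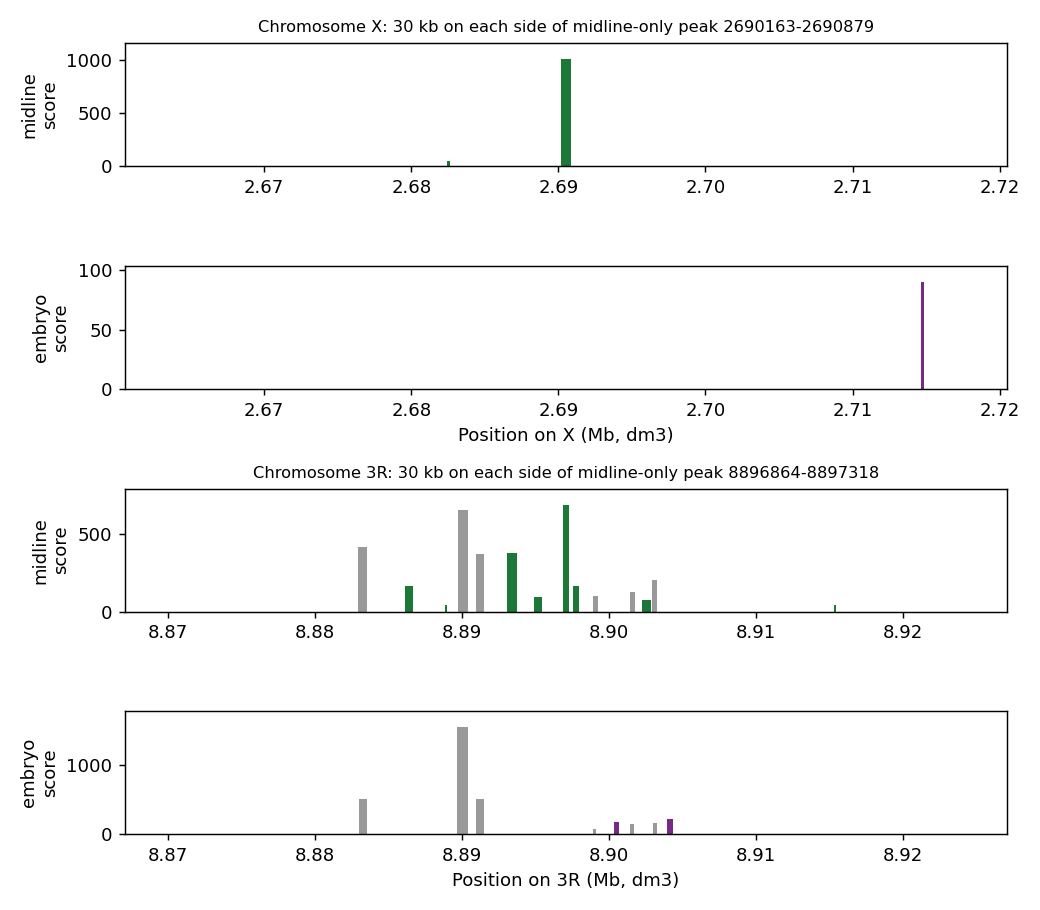
Peaks of the midline and embryo lists within 30 kb of the 2 highest-scoring midline-only peaks, drawn to scale along dm3 positions (x axis, Mb) with the authors' score as height (y axis, its own scale per list). Green is midline-only, purple embryo-only and grey shared. The X region holds a peak with a score of 1009 and 1 other midline-only peak, and the 3R region holds 8 midline-only peaks among 6 shared ones.

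The strongest embryo-only peaks ranked lower in their list than the strongest midline-only peaks did in theirs. The first, at positions 8454168 to 8454622 of 3R, had a score of 970 and ranked 133, and the nearest midline peak was 350 bp away. The second, at 15547155 to 15547699 of 3L, had a score of 850 and lay 11.3 kb from any midline peak. The remaining 3 were on the X at 17606877 to 17607443 (score 837), on 2R at 6012157 to 6012807 (score 798) and on 2L at 14039974 to 14040645 (score 750). By the peak numbers, the longer midline list held 0 further peaks between the flanking midline peaks of the first and the fifth of these, and 1, 2 and 1 for the second, the third and the fourth.

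The X chromosome carried fewer of the midline-only than of the embryo-only peaks. It held 506 midline-only peaks (12.9%, 11.9 to 14.0%) and 907 embryo-only peaks (20.9%, 19.7 to 22.1%), an odds ratio of 0.56 (two-sided Fisher's exact test, adjusted p = 2.93e-21). Of shared midline peaks, 17.4% lay on the X. Over the whole lists the X share was 15.7% for the midline and 19.0% for the embryo, a gap of 3.35 points, but in the longer lists the gap by the peak numbers was 0.88 points. The share of midline-only peaks was higher on 3L (22.7 against 19.4%, Fisher's exact test, adjusted p = 8.75e-04), 2L (19.9 against 17.2%, adjusted p = 0.00298) and 3R (25.3 against 23.2%, adjusted p = 0.0358). On 2R the shares were 19.2 and 19.3% (Fisher's exact test, adjusted p = 0.978). Shares sum to the whole over the arms, so the autosomal differences are not independent of that on the X. In counts, 3R held 988 midline-only and 1007 embryo-only peaks, against 886 and 844 on 3L and 779 and 748 on 2L. The higher share on 3R may therefore only mirror the lower share on the X. Shares among autosomal peaks alone were not tested. Fisher's test treats peaks as independent, but list-only peaks of the same class cluster (below), so the p-values by arm are too small. The embryos were not labelled by sex, and the input DNA was from females.

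**Figure D3:**
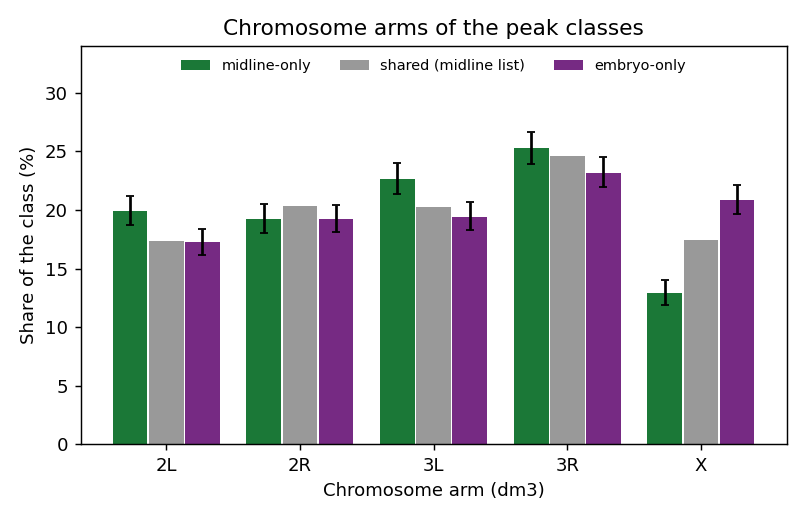
Share of midline-only (green), shared (grey, midline list) and embryo-only (purple) peaks (y axis, percent of each class) on each chromosome arm of dm3 (x axis). Bars on the green and purple columns are exact 95% binomial intervals. On the X the midline-only share is 12.9% and the embryo-only share 20.9%.

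List-only peaks of the same class lay next to each other more often than random classes would. Along the arms, 58.6% of 8248 neighbouring pairs of list-only peaks were of the same class, against 50.7 ± 0.54% (SD) when the classes were reassigned within each arm. The highest of 1000 reassignments was 52.4% (one-sided permutation p = 0.001, the smallest they can give). With a reciprocal overlap of 50% as the rule for sharing, the excess was no longer detected (permutation p = 0.34). Under that rule, 1267 of 10645 neighbouring pairs overlap each other and are of different classes by construction. The reassignments do not keep this, so that comparison cannot decide whether the excess depends on the rule. Single windows of 50000 bp did not pass the threshold. Of 487 windows tested, 0 passed after adjustment in the exact binomial test, and 60 had an unadjusted p under 0.05, of which 35 leaned to the midline and 25 to the embryo. At most about 24.4 are expected by chance. The most uneven window towards the midline was at 450001 to 500000 of 3L, with 11 midline-only and 0 embryo-only peaks (exact binomial test, adjusted p = 0.098). The most uneven towards the embryo was at 12550001 to 12600000 of the X, with 0 midline-only and 11 embryo-only peaks (exact binomial test, adjusted p = 0.098). Even these windows, each with list-only peaks of a single class, did not pass. The 0 calls at this size therefore do not show that the classes are evenly spread.

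**Figure D4:**
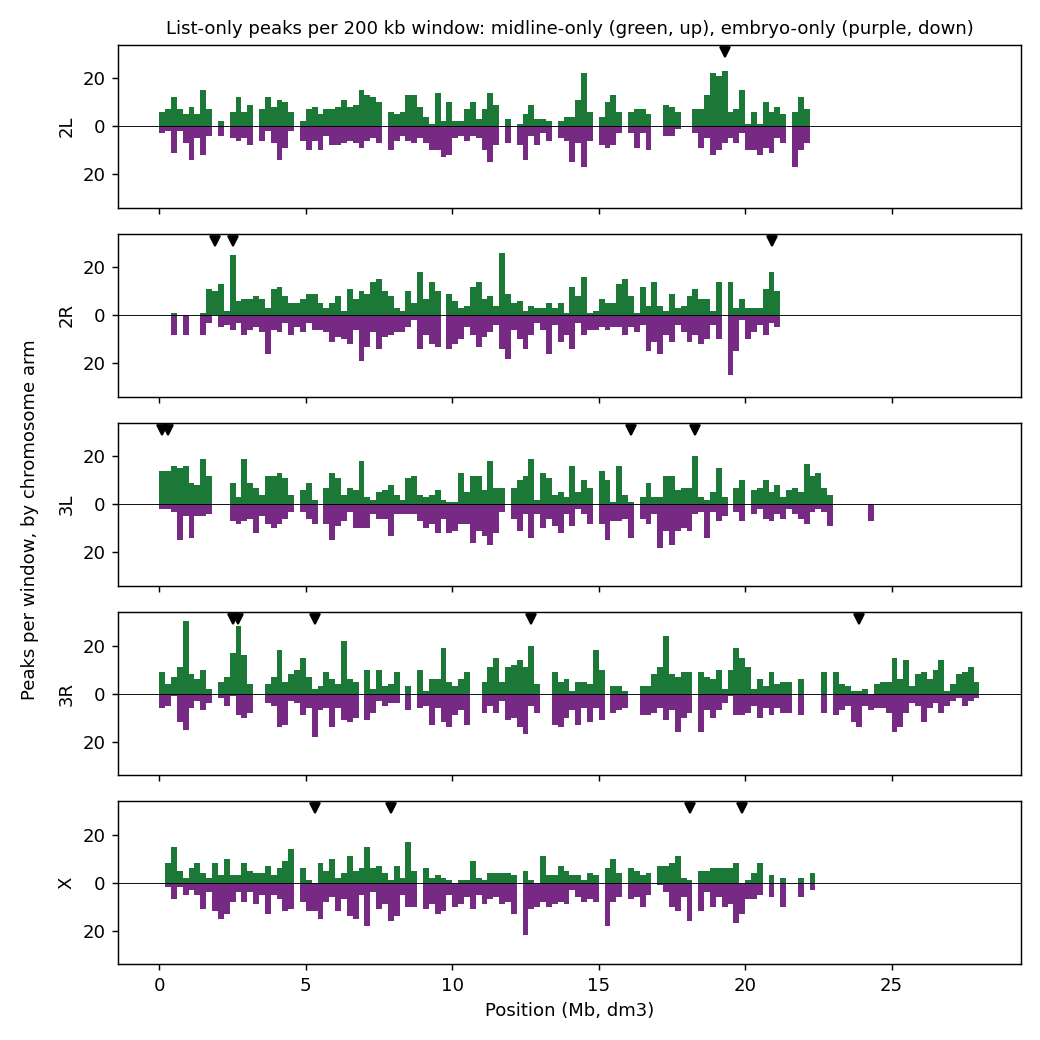
Midline-only (green, upward) and embryo-only (purple, downward) peaks per window of 200000 bp (y axis, peaks) along each chromosome arm (x axis, Mb, dm3), for windows with at least 6 list-only peaks. Triangles mark the 17 windows past the adjusted threshold at this window size, 10 towards the midline and 7 towards the embryo, of which 4 are on the X.

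Wider windows gave calls against the genome-wide proportion. At 100000 bp, 5 of 662 windows passed. The embryo window among them was at 12500001 to 12600000 of the X, with 0 midline-only and 18 embryo-only peaks (exact binomial test, adjusted p = 0.0073). The 4 towards the midline were on 2R at 2400001 to 2500000 (22 midline-only against 4 embryo-only peaks), on 3L at 1400001 to 1500000 (15 against 1) and 400001 to 500000 (14 against 1), and on 3R at 2500001 to 2600000 (11 against 0). When each window was compared with the proportion of its own arm, 0 of the 662 passed (exact binomial test, smallest adjusted p = 0.075, 78 with an unadjusted p under 0.05). At 200000 bp, 17 of 521 windows passed against the genome-wide proportion and 1 against that of the own arm.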

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

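The relation of sharing to strength, the correlation of ranks and the lower X share of midline-only peaks kept their direction, and where tested their side of the threshold, under each alternative run for them. For sharing and strength these were only the reciprocal overlap of 50% and the peak width, and neither removes the limit on list length. For the correlation of ranks the only alternative was a correlation of peak widths (Spearman 0.61). That is a different quantity, so the ranks by score were not retested. The share of midline peaks that were shared ranged from 46.8% with a reciprocal overlap of 50% to 82.2% for the 5000 highest-scoring peaks against the whole embryo list, and that of embryo peaks from 46.8 to 79.4%, so that shared peaks were the minority under the first rule. The X odds ratio ranged from 0.50 among the 5000 highest-scoring peaks to 0.75 among peaks between consecutively numbered peaks of the other list (Fisher's exact p = 0.0112). That p-value is too small as well, since the test treats clustered peaks as independent. The gap in X share between the whole lists was 3.35 points, and 0.88 points between the longer lists. The calls of single windows depended on window size and on the reference proportion, all settings chosen after seeing the data. There were 0 at 50000 bp, 5 at 100000 bp, 17 at 200000 bp, and against the proportion of the own arm 0 at 100000 bp and 1 at 200000 bp. The other window settings (moved by 25000 bp, at least 4 peaks, own arm at 50000 bp, reciprocal overlap of 50%) gave 0. The excess of neighbouring pairs of the same class was 7.91 points, 6.67 for pairs over 5000 bp apart and 0.19 with reciprocal overlap of 50%. Under that last rule, 1267 of 10645 neighbouring pairs were a midline and an embryo peak that overlap each other, which by its construction are of different classes. The alternatives planned for promoters, gene lists, genes with an excess and motifs were not run, since they need a dm3 annotation or sequence. No paired analysis was possible because the authors pooled the replicates before calling peaks, and for the same reason no replicate could be left out. Depth is unknown, so whether a peak missing from both a list and its longer set was closed or only undetected cannot be said.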

Other observations

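The share of longer-list peaks on the X, the number of midline-only peaks between consecutively numbered embryo peaks, and the runs and arm ends described here were chosen after the results were seen.

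Some stretches held peaks of a single list. On 3L, 23 embryo-only peaks followed each other from 23011171 to 24488284, a span of 1.48 Mb without a midline peak, and the longer midline list had left out 1 peak between the flanks. On 2R, 16 embryo-only peaks ran from 558343 to 1194886, with 3 midline peaks left out. On the X, 14 embryo-only peaks ran from 19799336 to 19999930, a span of 201 kb in which the longer midline list held 0 further peaks. The highest score was 113 in the 3L run, 324 in the 2R run and 134 in the X run. The median of the embryo list was 154, so all peaks of the 3L and X runs were weak for that list. The longest midline-only runs were shorter, with 10 peaks from 26611 to 78940 of 3L, 9 from 11337815 to 11400991 of 3R and 8 from 19897423 to 19934315 of 2L. Their highest scores were 232, 141 and 415 in that order, against a median of 95 in the midline list. The longer embryo list had left out 4 peaks between the flanks of the 3R run and 1 for the 2L run, and the 3L run has no embryo peak before it to count from. No test was made of these runs, which were picked for their length.

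In the 2 Mb at the centromere-side end of the arms, midline-only and embryo-only peaks had shares over all arms of 4.93 and 5.53% (Fisher's exact test, unadjusted p = 0.24). That end was the first 2 Mb of coordinates on 2R and 3R, and the last 2 Mb before the outermost peak on 2L, 3L and X. Distance to the centromere itself was not measured. By arm, 3R held 9.21% of its midline-only and 5.96% of its embryo-only peaks, and 2L 5.01 and 8.16% (Fisher's exact test, adjusted p = 0.017 and 0.022 over the 5 arms). The X held 4.55 and 4.74%, and 2R 3.19 and 4.78% (Fisher's exact test, adjusted p = 0.90 and 0.16). The 1.81 and 4.27% on 3L (Fisher's exact test, adjusted p = 0.014) are not independent evidence, since that part holds the embryo-only run just described, and the same is true of 2R. Fisher's test treats clustered peaks as independent, and single windows carry much of the other differences as well. The window from 800001 to 1000000 of 3R holds 30 midline-only and 15 embryo-only peaks, and that from 21600001 to 21800000 of 2L holds 6 and 17, so the p-values by arm are too small.

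A peak could be list-only because the other list stops at 10000 peaks. Of the embryo-only peaks, 30.4% (1319 of 4342) lie between consecutively numbered midline peaks, where the longer midline list had no further call. The limit cannot account for these, and the share is over the bound of 20% set beforehand. Shifted peaks passed that bound too (below), so it does not decide the matter for the class. For midline-only peaks the same holds for 774 of 3911 (19.8%), which the limit cannot account for, although the share is just under the bound of 20% set beforehand for the class. The other 3126 midline-only peaks with flanks on both sides lie where at least 1 embryo peak was left out, so the limit stays open for them. If each left-out peak matched at most 1 list-only peak, the limit would leave at least 1234 midline-only (31.6%) and 2158 embryo-only peaks (49.7%) unexplained. Among kept peaks that premise does not always hold, since 424 embryo peaks spanned several midline peaks and 37 midline peaks several embryo peaks. These minima therefore hold only under the premise. Shifted peaks fell between consecutive peaks of the other list more often, in 28.6% of cases for midline-only peaks (range over 1000 shifts 25.2 to 32.0%) and 35.6% for embryo-only peaks (32.8 to 38.3%), which is consistent with part of both classes being weak peaks of the other list below the limit.

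The lower X share of the midline list (15.7 against 19.0% of 10000 peaks, a gap of 3.35 points) may owe most of its size to the limit. In the longer lists the gap was 0.88 points, because the limit kept 67.4% of embryo X peaks and 55.0% of embryo autosomal peaks, but 67.9 and 65.5% in the midline list. Shared X peaks also ranked higher in the embryo list, by a median of 311 ranks relative to shared autosomal peaks (two-sided permutation p = 3e-05). Of the shared pairs, 56.3% on the X and 49.9% on the autosomes ranked higher in the embryo list. Peaks missing from a single list may therefore not be the whole pattern. The test treats peaks as independent, so its p-value may be too small. Embryo-only peaks outnumbered midline-only peaks in 11 of the 12 bins of 2 Mb along the X. They also did so over all arms (4342 against 3911), so that count alone cannot decide whether a local region carries the gap. Distant bins leaned to the embryo (61 midline-only against 111 embryo-only peaks at 6 to 8 Mb, 43 against 102 at 18 to 20 Mb). The lean was small or reversed in others (54 against 63 at 16 to 18 Mb, 59 against 52 at 0 to 2 Mb). Why X peaks score higher in the embryo list stays open, as strain, sorting, the sex ratio of the embryos and cell type all differ or are unrecorded, and none was tested.

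The strongest midline-only peaks could be open chromatin of midline cells, or could reflect extra copies of transgene sequence in the sorted strain, which the OregonR embryos lack. A fragment of several kilobases would give companion peaks, and 5 of the 5 highest-scoring midline-only peaks had another midline-only peak within 10000 bp. Of all midline-only peaks 65.5% do, so the test separates the explanations poorly. They cannot be told apart here without a dm3 annotation and the transgene sequences. The X peak with a score of 1009 is the first to look up, since it is the highest of the midline list and no kept embryo peak lies within 23.8 kb, although the longer embryo list held 1 peak between the flanks.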
